A study of Homo sapiens with 15 samples.

How the data were processed

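Chromatin from MDA-MB-231 cells was sonicated and immunoprecipitated with antibodies to H3K4ox (2 libraries), H2A.Z (1) and RUVBL2 (1), per the labels' protocols. Each library had its own deposited peak list, so replicates were not pooled. Samples were grouped by the antibody given in the labels. Of the 15 samples in the series, 4 had a list and 11 had none that was analysed here, namely 1 input, 8 RNA-seq and 2 ATAC-seq samples. The knockdown comparisons were therefore not analysed here.

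Peaks were named after the caller MACS, per the file headers and peak names, and its version and settings are not given in the sources used here. The submitters' processing notes name hg19, Bowtie and TopHat, with no versions or roles. The deposited score of each peak was the authors' own, written by the caller, and its unit is not given in the sources used here. The lowest score was 50 in each list, which points to a common minimum. Several peaks shared the value 3100. The scores were used to rank peaks or to divide them within a list, and to correlate scores between lists over matched peaks. The header lines of the 4 lists hold the word multilocus, whose meaning is not given in the sources used here, and only those of the H3K4ox lists name an input. Reads that map to many places, or calling without an input, would add peaks at repeats, at collapsed assembly sequence and at amplified segments. All lists lay on 24 chromosomes, and peaks within a list did not overlap.

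Intervals were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Peaks were counted as overlapping when they shared at least 1 bp. H3K4ox shared regions were merged peaks of both replicates that held at least 1 peak of each. For each overlap, the peaks of 1 list were moved to random positions within the outermost peaks of their own chromosome, keeping their widths, and the share overlapping was recomputed in 1000 shuffles. The log2 ratio of the observed to the mean random share was the value, and the p was two-sided with a smallest possible value of 0.002. Binomial intervals are Wilson intervals at 95%, cover counting error only and treat peaks as independent. Positions are counted from 1. No library had a known depth, so precision is given by peak numbers and by the 2 H3K4ox replicates.

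The shuffling was tested on simulated data in which a known share of peaks was placed in the target regions. With 30% placed, the mean log2 ratio recovered for lists like that of H2A.Z was 1.49 against 1.50 expected, and for lists like that of RUVBL2 1.42 against 1.42. With 5% placed, 20 of 20 lists of each kind passed the threshold, and with none placed 0 of 20 and 1 of 20 did. The simulated lists used the same random placement as the test. They check the calculation, not whether that placement suits real peaks, which cluster along the genome.

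Other settings tried were a covered share of 50% of the moved peak, 200 bp intervals at the centres, the upper 50% of each list by score, random positions within 500 kb of the real one, lists of equal length, and leaving out each H3K4ox replicate. These settings and the overlap tests were fixed before the data were examined. Densities per chromosome, windows of 1 Mb and 5 Mb, zones of 1 Mb next to 22 peak-free stretches of at least 1 Mb (133.8 Mb in all) and at chromosome ends, peaks of 800 to 900 bp, the test inside and outside H3K4ox shared regions and the study of 1 stretch of chromosome 5 were added after seeing the data. For the zones, random positions left out the peak-free stretches. The starts of chromosomes 13, 14, 15, 21 and 22, where no list had a peak for many Mb, were counted with the zones next to peak-free stretches. H2A.Z peaks of score 600 or more were grouped where they lay within 50 kb of each other, and the group with the most peaks was described.

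Of the planned results, 12 needed a genome or gene annotation of hg19 and were not run, since none was used here: the share of peaks at promoters, gene density, repeat content and the 23 gene lists, for each antibody. The lists of cell type markers could not be applied for the same reason. By the rule fixed before the data were examined, sites were then named by position, as the 10 best-ranked sites of each antibody and the 10 best sites of all 3, and the text gives part of these. For H3K4ox the rank was the mean of both replicates.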

Results

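The series examined MDA-MB-231 cells, an established line of triple-negative breast cancer that grows as mesenchymal-like cells. Its title names LOXL2, a lysyl oxidase that acts on lysine 4 of histone H3 and leaves the oxidised form H3K4ox, and chromatin compaction. Of the 15 samples, 4 had a peak list from chromatin immunoprecipitation with sequencing (ChIP-seq), made with 3 antibodies: 2 lists for H3K4ox, 1 for the histone variant H2A.Z and 1 for RUVBL2. RUVBL2 is an ATPase found in the complexes that exchange H2A.Z in nucleosomes. The input library, the 8 RNA-seq libraries, of control cells and of cells with LOXL2 or RUVBL2 knocked down, and the 2 ATAC-seq libraries were not analysed here. Sequencing depth was unknown, since the lists hold peaks and no reads. H2A.Z and RUVBL2 had no replicate, and for H3K4ox nothing stated that the 2 libraries came from separate cultures, so their spread may be technical.

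H3K4ox gave the most peaks and H2A.Z the fewest. The H3K4ox lists held 249713 ± 3883 peaks (SD, n = 2), the RUVBL2 list 109607 and the H2A.Z list 38584. The peaks covered 262.7 ± 10.7 Mb (SD, n = 2) for H3K4ox, 122.6 Mb for RUVBL2 and 35.0 Mb for H2A.Z, within a span of 3010 Mb between the outermost peaks of the chromosomes. Peaks were of similar width, with medians of 830 ± 16 bp (SD, n = 2) for H3K4ox, 870 bp for RUVBL2 and 808 bp for H2A.Z. A design of 2 lists against 1 cannot give a two-sided exact permutation p below 0.33, so the list sizes were not tested. They also depend on depth and on how each list was called.

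The H3K4ox lists were compared first, to find which sites both libraries held. Of the peaks of replicate 1, 67.8% overlapped a peak of replicate 2, and 70.2% of the peaks of replicate 2 overlapped one of replicate 1. The mean was 69.0% ± 1.7 (SD, n = 2), against 18.8% when the peaks were placed at random on their own chromosome, a 3.67-fold difference (log2 ratio 1.88, two-sided permutation p = 0.002, the smallest that 1000 shuffles give). Merging both lists gave 317583 regions, of which 162645 (51.2%, together 231.1 Mb) held peaks of both libraries and are called H3K4ox shared regions here. Agreement rose with the score that the authors' peak caller gave each peak. Peaks of each list were divided by score into 10 groups of equal size, from group 1 (lowest) to group 10 (highest). In group 1, 41.2% ± 2.7 of peaks (SD, n = 2) were found in the other replicate, and in group 10, 99.9% ± 0.03 (SD, n = 2). No peak had the same start and end in both lists. Over the shared regions the scores of the replicates had a Spearman correlation of 0.71 across regions, which are not independent replicates. Placing 200 bp intervals at the peak centres lowered the observed share to 51.8% and the random share to 3.90%, a 13.3-fold difference, and requiring 50% of the moved peak to be covered gave 6.69-fold. Random positions within 500 kb gave 2.71-fold.

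The next comparison asked whether RUVBL2 lay where H3K4 was oxidised. RUVBL2 was the antibody with the larger share of peaks in H3K4ox shared regions: 70623 of 109607 RUVBL2 peaks (64.4%, 95% Wilson interval 64.1 to 64.7) overlapped one, against 14.9% at random positions. The difference was 4.31-fold (log2 ratio 2.11, two-sided permutation p = 0.002). In the other direction, 38.5% of the shared regions held a RUVBL2 peak. RUVBL2 peaks inside the shared regions were wider (median 1011 bp against 743 bp outside) and had higher scores (median 90.8 against 60.9). With each list reduced to the 38584 best-scoring peaks, 53.3% of RUVBL2 peaks lay in H3K4ox shared regions against 4.76% at random, an 11.2-fold difference. Intervals of 200 bp at the centres gave 10.8-fold, coverage of 50% of the moved peak 7.02-fold and the upper 50% of each list by score 6.81-fold. Lower values came from random positions within 500 kb, with 3.08-fold (20.9% at random). Leaving out H3K4ox replicate 1 gave 3.93-fold and leaving out replicate 2 gave 3.85-fold.

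Overlap between RUVBL2 and H3K4ox rose with the score of either. Among RUVBL2 peaks it went from 42.0% in score group 1 to 98.2% in group 10, and among H3K4ox peaks from 13.1% ± 0.8 to 79.5% ± 0.2 (SD, n = 2). High-scoring peaks are also wider and so meet other peaks more often. Among RUVBL2 peaks of 800 to 900 bp the share still rose, from 40.0% of 970 peaks in group 1 to 73.7% of 566 peaks in group 8. Among H3K4ox peaks of that width the rise was small and ended: in replicate 1 the share was 16.1% in group 1, 25.5% in group 8 and 11.8% of 170 peaks in group 10, and in replicate 2 it was 18.6%, 26.0% and 9.84% of 183 peaks.

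**Figure D1:**
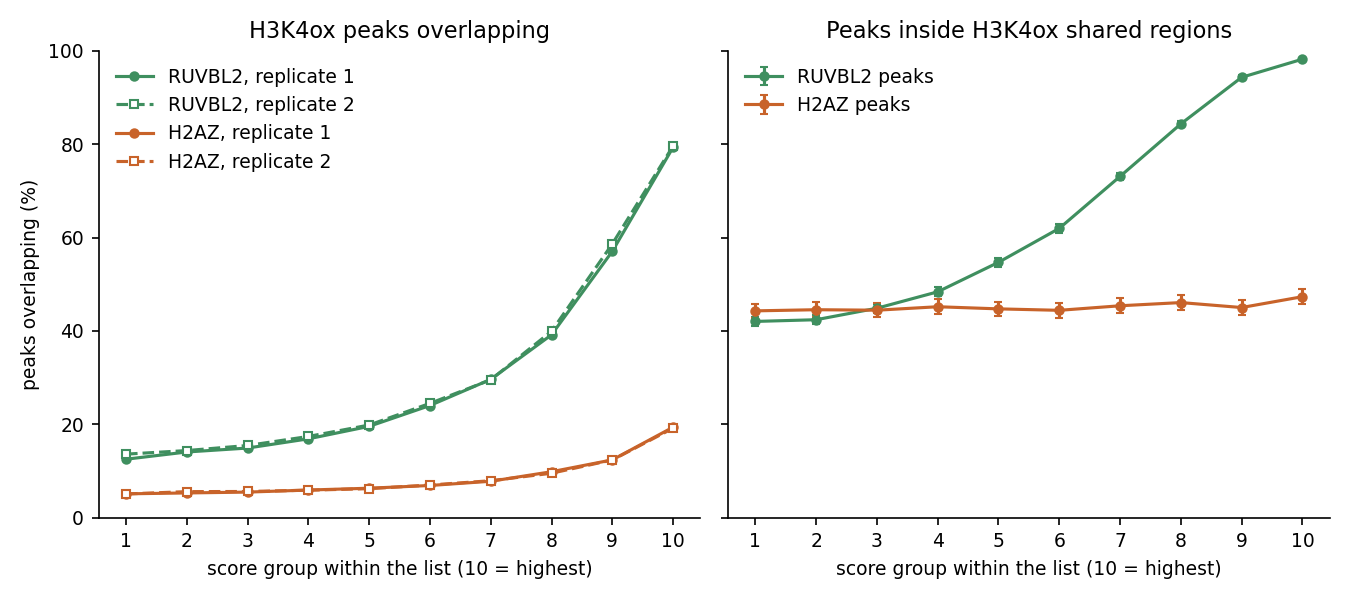
Share of peaks that overlapped another list (vertical axis, %) by score group within each list (horizontal axis, 10 groups of equal size, 10 is the highest). Left, H3K4ox peaks of each replicate overlapping RUVBL2 or H2A.Z (written H2AZ) peaks; right, RUVBL2 and H2A.Z peaks inside H3K4ox shared regions, with 95% Wilson intervals as bars. RUVBL2 peaks rise from 42.0% to 98.2%, while H2A.Z peaks stay between 44.3% and 47.3%.

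H2A.Z peaks were also found in H3K4ox shared regions more often than at random. Most lay outside these regions, but 55.2% overlapped an H3K4ox peak of replicate 1 and 53.6% one of replicate 2. Of the 38584 H2A.Z peaks, 17422 (45.2%, 95% Wilson interval 44.7 to 45.7) overlapped a shared region, against 13.9% at random positions, a 3.24-fold difference (log2 ratio 1.70, two-sided permutation p = 0.002). The shared regions are far more numerous than H2A.Z peaks, and 10.3% of them held one. Unlike RUVBL2, the H2A.Z share hardly moved with the H2A.Z score: it was 44.3% in score group 1 and 47.3% in group 10. H3K4ox peaks overlapped H2A.Z more often at higher H3K4ox scores, from 5.12% ± 0.02 to 19.3% ± 0.2 (SD, n = 2). Median widths rose with score too, from 657 to 2234 bp in H3K4ox replicate 1 and from 637 to 1361 bp in H2A.Z. Wider peaks meet others more often at random, and H2A.Z overlap was not compared at matched width. Intervals of 200 bp at the centres gave an 8.30-fold difference. With lists of equal length the H2A.Z share fell to 15.8%, against 3.95% at random, a 3.99-fold difference. Lower values came from random positions within 500 kb, with 2.38-fold (18.9% at random). Leaving out H3K4ox replicate 1 gave 3.17-fold and leaving out replicate 2 gave 3.13-fold.

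The remaining pair was H2A.Z with RUVBL2, which belongs to H2A.Z exchange complexes. Of the H2A.Z peaks, 12885 (33.4%, 95% Wilson interval 32.9 to 33.9) overlapped a RUVBL2 peak, against 8.13% at random, a 4.11-fold difference (log2 ratio 2.04, two-sided permutation p = 0.002). Of the RUVBL2 peaks, 11.8% overlapped H2A.Z. The overlap was more frequent inside H3K4ox shared regions, where 57.0% of 17422 H2A.Z peaks met a RUVBL2 peak, than outside, where 14.0% of 21162 did. Relative to random positions of the same class the order was opposite, with 1.41-fold inside (40.5% at random) and 4.82-fold outside (2.90% at random), each with a two-sided permutation p of 0.002. With 40.5% at random, even complete overlap inside would give a ratio below 4.82. The order of the ratios therefore cannot show a stronger association outside. The difference between inside and outside was not tested. Intervals of 200 bp at the centres gave a 9.48-fold difference over all H2A.Z peaks (15.8% against 1.67%), and coverage of 50% of the moved peak 6.35-fold. Random positions within 500 kb gave 2.905-fold.

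Sites with H3K4ox, H2A.Z and RUVBL2 together made up 9925 of the H2A.Z peaks (25.7%, 95% Wilson interval 25.3 to 26.2), against 5.63% when H2A.Z peaks were placed at random. The difference was 4.57-fold (log2 ratio 2.19, two-sided permutation p = 0.002). Only H2A.Z peaks were moved, and H3K4ox and RUVBL2 kept their own overlap, so this value is not independent of the pairwise tests. A further 7497 H2A.Z peaks (19.4%) lay in H3K4ox shared regions without RUVBL2. Outside the shared regions, 2960 (7.67%) met RUVBL2 and 18202 (47.2%) did not. Some peaks outside still met H3K4ox, since 21285 H2A.Z peaks overlapped a peak of replicate 1 and 17422 a shared region. The 4 classes had similar median scores, between 66.0 and 67.8, and similar median widths, between 786 and 848 bp. Across the 5 overlap tests the Benjamini-Hochberg adjusted p was 0.002. These tests describe how the peaks of these libraries lay on the genome, not a spread between cultures. With 200 bp intervals the three-way difference was 14.0-fold, from an observed share of 5.45% against 0.39%. With random positions within 500 kb it was 3.06-fold.

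**Figure D2:**
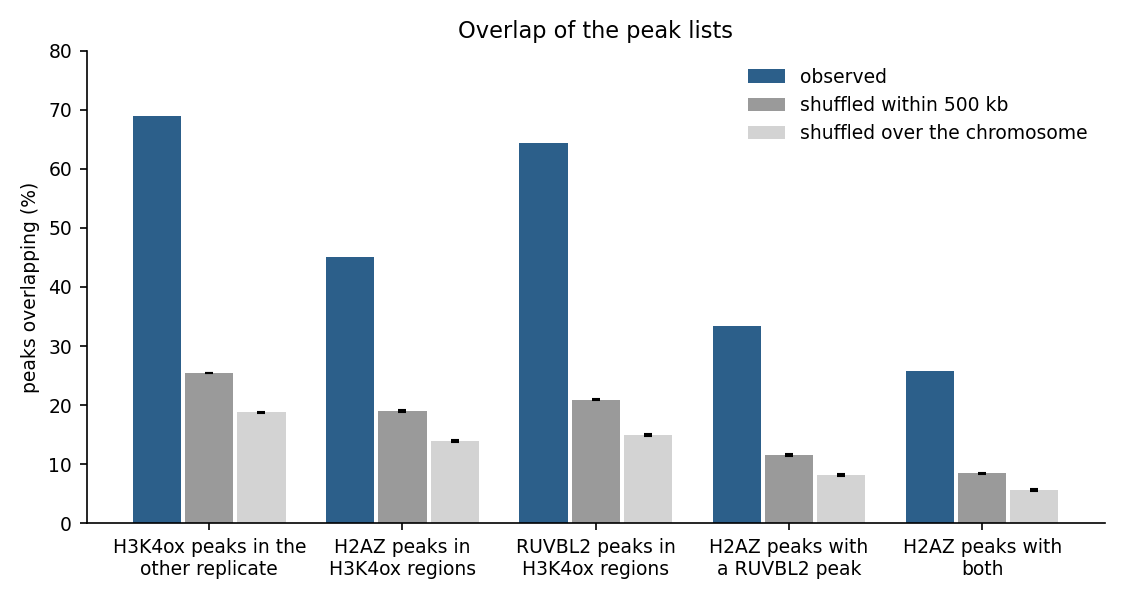
Share of peaks that overlapped another list (vertical axis, %) for 5 comparisons (horizontal axis), as observed, with peaks shuffled within 500 kb and with peaks shuffled over their chromosome; bars on the shuffled values are the SD of 1000 shuffles. The observed share is above both random shares in each comparison, for example 64.4% against 20.9% and 14.9% for RUVBL2 peaks in H3K4ox shared regions.

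The overlap was centred on the peaks. H3K4ox shared regions covered 43.0% of H2A.Z peak centres and 15.2% of positions 20 kb before them, and RUVBL2 peaks covered 29.4% of H2A.Z centres and 8.25% at that distance. At RUVBL2 centres the H3K4ox coverage was 62.3%, and 15.1% at 20 kb.

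**Figure D3:**
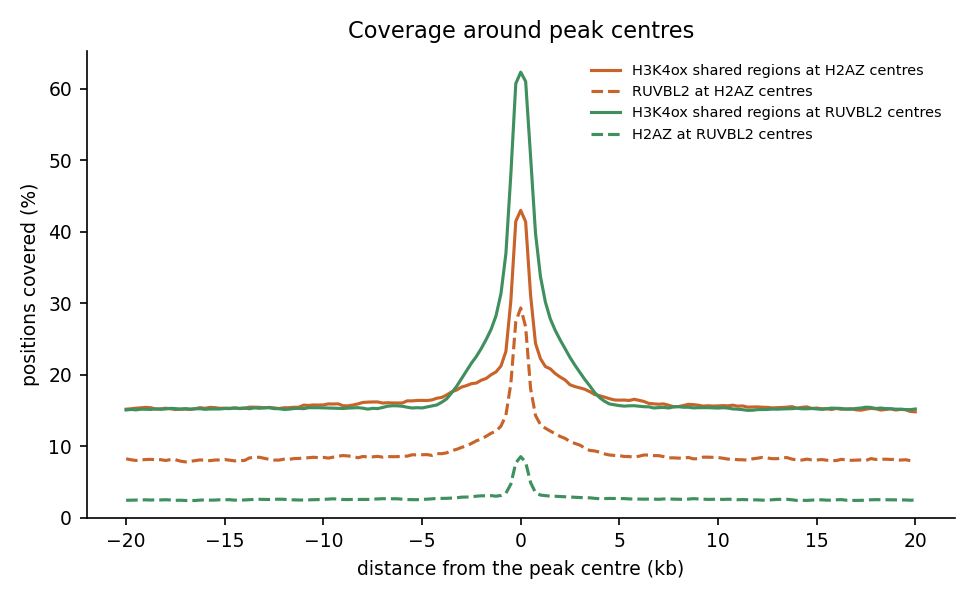
Share of positions covered by another list (vertical axis, %) by distance from peak centres (horizontal axis, kb), for H2A.Z centres and RUVBL2 centres. H3K4ox coverage peaks at 62.3% over RUVBL2 centres and 43.0% over H2A.Z centres and levels off near 15.2%.

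Along the genome, the 3 antibodies had their highest peak density on chromosome 19, which held 240.7 ± 0.8 H3K4ox peaks per Mb (SD, n = 2), 38.0 H2A.Z peaks per Mb and 105.8 RUVBL2 peaks per Mb. These were 2.75, 2.81 and 2.76 times the mean density of chromosomes 1 to 22 and X. Chromosome 17 came next for H3K4ox (2.11 times) and was also high for H2A.Z (1.65) and RUVBL2 (1.87). Chromosome X was low for H3K4ox (0.32) and H2A.Z (0.31) and less so for RUVBL2 (0.62), and chromosome 13 was low for the 3 antibodies (0.50, 0.73 and 0.43). On chromosome 19, 77.6% of H2A.Z peaks lay in H3K4ox shared regions, against 16.6% on chromosome 13. Chromosome 13 held only 43.8 H3K4ox peaks per Mb, which lowers the share at random, and no random share was computed per chromosome. The comparisons along the genome were chosen after the lists had been examined.

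The antibodies parted on some chromosomes. Chromosomes 4 and 6 were below the mean for H3K4ox (0.77 and 0.75) and above it for H2A.Z (1.34 and 1.46), and on chromosome 6 RUVBL2 was above it too (1.24). Chromosome 15 was above the mean for H3K4ox (1.36) and below it for H2A.Z (0.54) and RUVBL2 (0.65), and chromosome 22 followed the same order (1.15, 0.54 and 0.57). In the upper 50% of each list by score, however, H3K4ox was below the mean on chromosome 22 (0.95 ± 0.03, SD, n = 2), as were H2A.Z (0.58) and RUVBL2 (0.37). Relative densities of the H3K4ox replicates had an SD of at most 0.014 on these 4 chromosomes, but H2A.Z and RUVBL2 had 1 library each, so the differences were not tested.

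**Figure D4:**
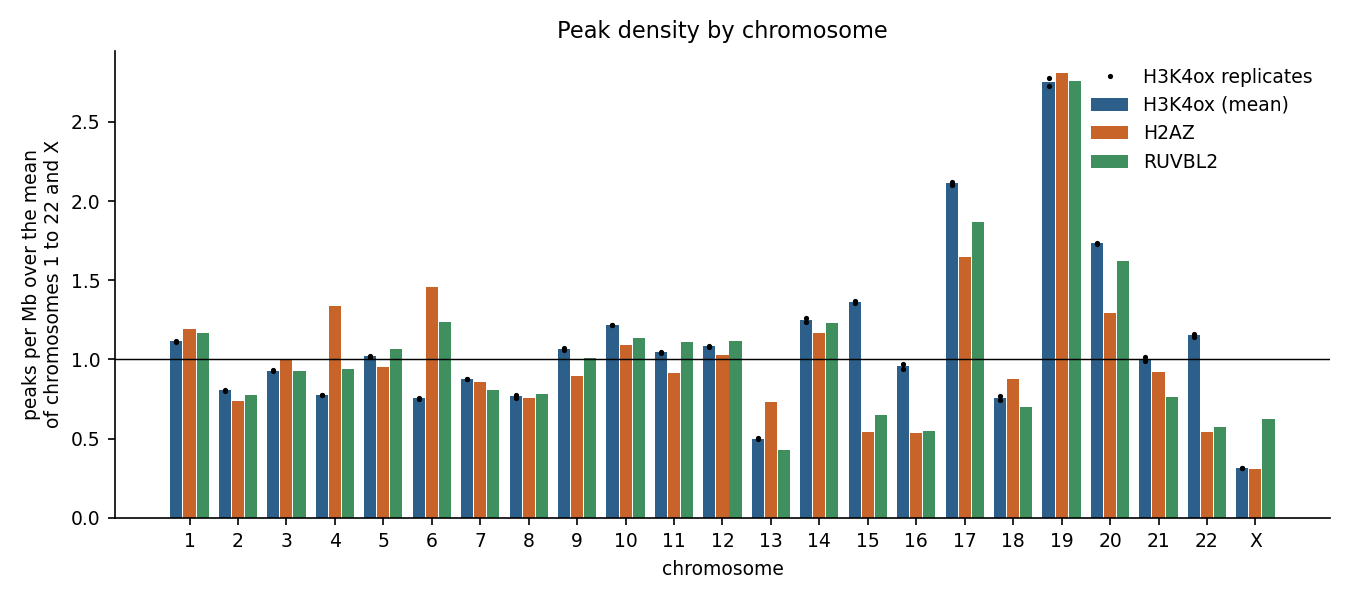
Peak density of each chromosome (horizontal axis) as peaks per Mb divided by the mean of chromosomes 1 to 22 and X (vertical axis), with bars for H3K4ox (mean of 2), H2A.Z (written H2AZ) and RUVBL2 and points for the H3K4ox replicates. Chromosome 19 is highest for each antibody, at 2.75, 2.81 and 2.76, and chromosomes 4, 6, 15 and 22 show H3K4ox and H2A.Z on opposite sides of 1.

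In windows of 1 Mb the H3K4ox replicates followed each other closely (Spearman 0.99 over 2888 windows, which are not independent replicates). RUVBL2 followed H3K4ox with 0.71 and 0.72 for the 2 replicates, H2A.Z followed H3K4ox with 0.44 and 0.45, and H2A.Z followed RUVBL2 with 0.63. Within chromosomes, H2A.Z with H3K4ox had medians of 0.42 and 0.45 and lowest values of -0.20 and -0.18. H2A.Z with RUVBL2 had a median of 0.59 and a lowest value of 0.07. The dense part of chromosome 19 from 8 to 19 Mb held 331.4 H3K4ox, 84.7 H2A.Z and 222.2 RUVBL2 peaks per Mb. Of the 10 densest windows, chromosome 19 held 7 for H3K4ox, 9 for H2A.Z and 7 for RUVBL2, and the windows at 10, 11, 14 and 17 Mb were among them for each antibody. Relative to H3K4ox both other antibodies were more frequent where H3K4ox was sparse: the sparsest 10% of windows held 32.9 H2A.Z and 71.1 RUVBL2 peaks per 100 H3K4ox peaks, and the densest 10% held 13.5 and 42.3. The highest H2A.Z value was in the next sparsest group (34.0). The windows were grouped by the H3K4ox count that is also the denominator, which by itself raises the ratio in sparse windows. The share of H2A.Z peaks in H3K4ox shared regions went the other way, from 18.8% to 73.4%. For RUVBL2 it was 60.8% in the sparsest windows and 75.6% in the densest. Windows dense in H3K4ox also hold more for a peak to meet at random, and no random share was computed for these groups.

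The best-scoring sites mostly differed between antibodies, and are given by position in hg19, since no gene annotation of that build was used here. Among the 10 best of each, RUVBL2 shared sites with H3K4ox on chromosomes 1 and 17 and with H2A.Z on chromosomes 5 and 18. The shared site on chromosome 5 lay at a chromosome end and the others within 1 Mb of a long peak-free stretch. Reads that map to many places could add peaks to several lists there, so these sites need not show joint presence. Among the 10 best H3K4ox sites were chromosome 9 at 35912901 to 35914905 and chromosome 2 at 64602285 to 64603635, which both also held H2A.Z and RUVBL2 peaks, and chromosome 11 at 1092113 to 1094044 and chromosome 15 at 65243218 to 65247877, which held neither. Scores of 3100 were shared by several of these sites, so their order is not exact. Of the 10 best RUVBL2 peaks, 6 lay within 1 Mb of a long peak-free stretch, as at chromosome 18, 18510749 to 18520838 (score 3100), and 7 overlapped H3K4ox. A pair of wide RUVBL2 peaks on chromosome 8, at 86727362 to 86734972 and 86748932 to 86756460, lay in H3K4ox shared regions without H2A.Z.

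Of the 10 best H2A.Z peaks, 1 overlapped an H3K4ox shared region and 9 overlapped RUVBL2. Within chromosome 5, 126112951 to 126168746, a stretch of 55.8 kb, lay 10 H2A.Z peaks with scores from 626.4 to 3100, of which 5 were among the 10 best of the list. Each of the 10 met a RUVBL2 peak, none met a peak of H3K4ox replicate 1 and 1 met a peak of replicate 2. Elsewhere, 79 of 96 H2A.Z peaks with a score of 600 or more (82.3%) overlapped H3K4ox of either replicate. Other high H2A.Z peaks outside the shared regions were chromosome 15, 74218853 to 74220377 (score 2603, width 1525 bp), without RUVBL2, and chromosome 3, 190572892 to 190573912 (score 2197, width 1021 bp), with it. Wide ones lay next to peak-free stretches and met RUVBL2: chromosome 18, 18510749 to 18520788 (score 1679, width 10040 bp), and chromosome 6, 58773079 to 58780316 (score 1559, width 7238 bp). H2A.Z peaks of score 600 or more outside the chromosome 5 stretch had a median width of 2193 bp. Whether the best-scoring H2A.Z peaks come from the cells' chromatin was left undecided.

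**Figure D5:**
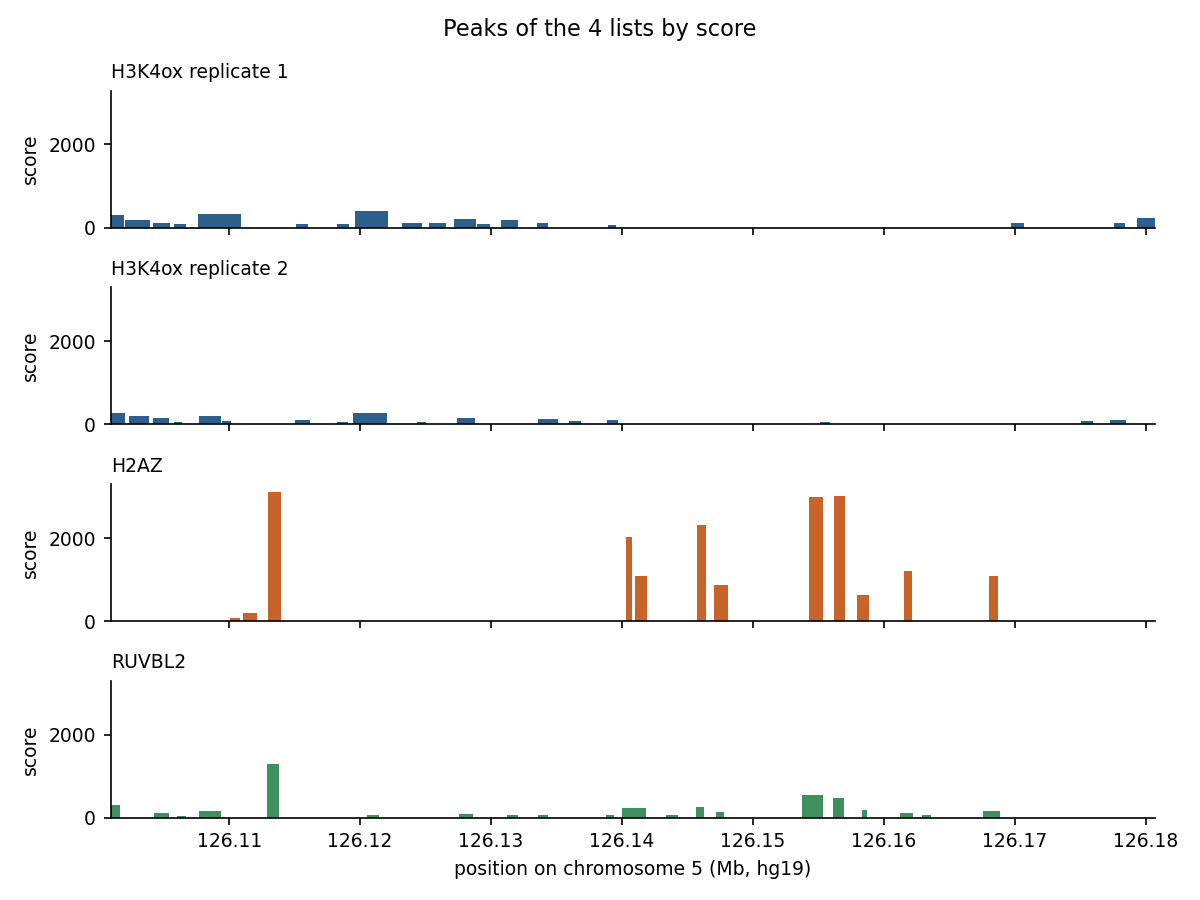
Peaks of the 4 lists on chromosome 5 around 126112951 to 126168746 (horizontal axis, Mb in hg19), drawn at their width with the authors' score as height (vertical axis). The 10 H2A.Z peaks of 626.4 or more stand above RUVBL2 peaks of up to 1293 at the same positions, while H3K4ox peaks in the map reach 401.4. Of the 35 H3K4ox peaks of both replicates, 16 lie outside the stretch, 18 between the first and second of the 10 H2A.Z peaks and 1 overlaps an H2A.Z peak.

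Sites ranked best for the 3 antibodies together included chromosome 5 at 9851 to 11946, at the end of the chromosome, chromosome 6 at 42884960 to 42890810 and at 42841166 to 42847547, chromosome 12 at 123941235 to 123944009, and 4 sites on chromosome 19: 15319952 to 15322371, 17335767 to 17337153, 18014547 to 18018108 and 18662599 to 18668595. Of the 10 best such sites, 2 lay at chromosome ends, that on chromosome 5 and 1 on chromosome 1 at 9873 to 10743. On chromosomes 1, 4, 5, 7 and 18 the first peak of each of the 4 lists began between bases 9851 and 9894. A start common to every list may come from mapping, so these 2 sites need not show joint presence of the 3 antibodies' targets.

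Regions next to long peak-free stretches, which include centromeres and assembly gaps, and regions at chromosome ends separated H3K4ox from the other antibodies. Within 1 Mb of peak-free stretches, H3K4ox peaks were less frequent than at random positions, at 0.81 ± 0.01 of the random level (SD, n = 2), while H2A.Z (1.202) and RUVBL2 (1.41) were more frequent. Within 1 Mb of chromosome ends H3K4ox was more frequent, at 1.11 ± 0.002 (SD, n = 2), and H2A.Z (0.75) and RUVBL2 (0.91) less so. Each of the 8 values had a two-sided permutation p of 0.002. The shuffles moved each peak on its own, while real peaks cluster, and there were only 43 zones next to peak-free stretches and 41 at chromosome ends. These p-values may therefore be too small, and they do not measure a spread between zones. Few peaks were involved, 1.92% of H2A.Z and 2.28% of RUVBL2 peaks near the peak-free stretches, and only the H3K4ox lists name an input in their header.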

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

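The tests of chromosome 5, of copy number and of weak peaks were chosen after their results were seen, and those of the regions next to peak-free stretches were written before.

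Some values stood on opposite sides of the genome-wide level in both H3K4ox libraries and in another antibody. None of these differences between antibodies was tested. Next to peak-free stretches the values relative to random were 1.202 for H2A.Z and 1.41 for RUVBL2, against 0.81 for H3K4ox, and at chromosome ends 0.75 and 0.91, against 1.11. H2A.Z density relative to the genome was 1.34 on chromosome 4 and 1.46 on chromosome 6, where both H3K4ox libraries were below 1, and 0.96 on chromosome 5, 0.90 on chromosome 9, 0.92 on chromosome 11, 0.54 on chromosome 15 and 0.54 on chromosome 22, where both were above 1. RUVBL2 was 1.24 on chromosome 6, 0.65 on chromosome 15 and 0.57 on chromosome 22. In the upper 50% of each list by score both H3K4ox libraries were below 1 on chromosome 22 too (0.97 and 0.93).

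For the uneven chromosomes, copy number that input correction removed from H3K4ox but not from the other lists is a possible explanation. It would move H2A.Z and RUVBL2 together. Relative to H3K4ox they stood on the same side of 1 on 16 of 23 chromosomes (15 in the upper 50% of each list). Among these were 4 (1.73 and 1.21 times), 6 (1.93 and 1.64), 15 (0.40 and 0.47), 16 (0.56 and 0.58) and 22 (0.47 and 0.50). They stood on opposite sides in both settings on chromosomes 5 (0.94 and 1.05), 8, 11 (0.88 and 1.06), 12 and X. In the full lists alone they did so on 13 (1.46 and 0.86) and 18 (1.16 and 0.93). No count expected without copy number was computed, and some ratios lay close to 1, as on chromosome 19 (1.02 and 1.003). Both ratios also share the H3K4ox density, which by itself tends to put them on the same side. The count therefore cannot decide. In 5 Mb windows the median log2 excess was 1.51 for H2A.Z and 0.48 for RUVBL2 where H2A.Z was high and -1.31 and -0.77 where it was low; these windows were chosen by H2A.Z, both ratios share the H3K4ox count and the lists differ in length, so copy number cannot be told apart from other causes common to both lists. On chromosome X it is argued against as the only cause of the RUVBL2 excess (1.97 times H3K4ox), since the log2 ratio of H2A.Z was -0.034 (95% counting interval -0.15 to 0.08) and -0.78 in the upper 50% of each list, where that of RUVBL2 was 0.97, and likewise for the H2A.Z excess on chromosome 13, where the log2 ratio of RUVBL2 was -0.21 (-0.28 to -0.14) and 0.07 in the upper 50%, against 0.54 and 0.81 for H2A.Z. Both arguments assume that lists of different length respond alike to copy number, and neither H2A.Z nor RUVBL2 had a replicate. Peaks near the minimum score are argued against as the cause on chromosome 6. There the log2 ratio of H2A.Z to H3K4ox was 0.95 in the full lists and 1.01 in their upper 50%. On chromosomes 4 and 15 this ratio went from 0.79 to 0.89 and from -1.33 to -1.25. The H2A.Z deficit shrank on chromosome 16 (-0.84 to -0.57) and 22 (-1.08 to -0.71). There the H3K4ox density relative to the genome fell, from 0.96 to 0.78 and from 1.15 to 0.95. That of H2A.Z changed less, from 0.54 to 0.53 and from 0.54 to 0.58. Weak H3K4ox peaks, more than weak H2A.Z peaks, may therefore add to the H2A.Z deficit there. The RUVBL2 deficit did not shrink on these chromosomes (-0.80 to -0.83 and -1.01 to -1.36). Base composition, mappability and a biological difference between the marks stay open and were not tested.

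For the regions next to peak-free stretches, a handful of very wide repeat peaks may account for the RUVBL2 excess, but RUVBL2 peaks of up to 5 kb were still 1.35 times as frequent there as at random, which argues against it. Use of the control during calling could also part the antibodies, since only the H3K4ox headers name an input. RUVBL2 peaks there overlapped H3K4ox shared regions in 60.6% of cases (95% Wilson interval 58.7 to 62.5), against 64.5% elsewhere (64.2 to 64.8), the lower share that the bound written beforehand asked for. H3K4ox peaks were themselves less frequent there, at 0.81 of the random level, which lowers this share whatever the cause. The bound therefore cannot decide whether the control was the cause. RUVBL2 peaks there were wider (median 1176 bp against 866 bp) and higher in score (95.9 against 73.05), and in a comparison chosen afterwards, with the peaks elsewhere weighted to the same scores and widths, the share elsewhere was 73.8%; a difference between the antibodies is not excluded, and no biological explanation was tested.

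The H2A.Z peaks of chromosome 5, 126112951 to 126168746, were singled out after their scores were seen. DNA from another source than the cells' chromatin, such as a construct, is a candidate explanation, as the 10 peaks had a median width of 874 bp, against 2193 bp for 96 H2A.Z peaks of score 600 or more elsewhere, a ratio of 0.40. The stretch was picked as the group with the most separate peaks of that score, which favours narrow peaks, and no other group held 3 or more, so added DNA cannot be told apart from a strong chromatin site, for which no biological explanation was tested. A source shared with the RUVBL2 library, whether chromatin or added DNA, would make the scores of both lists move together, and over the 10 peaks Spearman's rho was 0.82 (permutation p = 0.0058) and Pearson's r 0.74 (permutation p = 0.0004), with 0.67 and 0.84 without the 2 peaks farthest from the median; neighbouring peaks are not independent and 2 of them met the same RUVBL2 peak. The doubt is not confined to this stretch: it extends to other high-scoring H2A.Z peaks and to what their overlap with RUVBL2 means, such as the 17 of score 600 or more elsewhere that lay outside H3K4ox of either replicate, 6 of them with RUVBL2, and the input reads, which would show extra copies, were not analysed here.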

How the results depend on the processing

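The settings that left out peak-free stretches or the peaks near them and near chromosome ends, and those for zones and chromosomes, were chosen after seeing the data. The 5 overlaps kept their direction and a permutation p of 0.002 under the 40 alternatives run. Their log2 ratios ranged from 1.44 to 3.73 for the H3K4ox replicates, from 1.25 to 3.05 for H3K4ox with H2A.Z, from 1.62 to 3.49 for H3K4ox with RUVBL2, from 1.54 to 3.24 for H2A.Z with RUVBL2 and from 1.61 to 3.80 for the three-way overlap. The lowest values came from random positions within 500 kb, which keep regional density. The highest came from 200 bp intervals, except for H3K4ox with RUVBL2, where lists of equal length gave the highest. Leaving out an H3K4ox replicate gave 1.65 to 1.66 for H2A.Z, 1.95 to 1.97 for RUVBL2 and 2.18 to 2.19 for the three-way overlap. The 16 alternatives for zones kept their direction with a permutation p of at most 0.006, though sizes changed, as for RUVBL2 next to peak-free stretches (1.41 to 1.88 in the upper 50% by score). H3K4ox came closer to random there, from 0.81 and 0.82 in the 2 replicates to 0.92 and 0.94 in the upper 50%. Of the 14 for chromosomes, 11 moved beyond counting error; on chromosome 19 the ratios to H3K4ox, within counting error of 1 in the full lists (1.02 for H2A.Z and 1.003 for RUVBL2), fell below 1 (0.95 and 0.85), and H2A.Z on chromosome X went from 0.98 to 0.58. No paired analysis was possible because only the H3K4ox libraries had 2 lists, and the knockdown groups that share replicate numbers were not analysed here. The 41 alternatives for promoters, gene density, repeats and gene lists were not run, since no hg19 genome or annotation was used here. Depth was unknown, so list sizes and overlaps may differ with sequencing effort: with lists of equal length the log2 ratios were 2.00 for H3K4ox with H2A.Z, 3.49 for H3K4ox with RUVBL2, 2.26 for H2A.Z with RUVBL2 and 2.37 for the three-way overlap. Part of the overlap may also come from a control shared between lists or from mapping, which leaving out peaks near gaps and chromosome ends (log2 ratios 1.75 for H3K4ox with H2A.Z, 2.16 for H3K4ox with RUVBL2 and 2.08 for H2A.Z with RUVBL2) tests only in part, and which could not be simulated without reads.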

Other observations

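Segments of 5 Mb with many H2A.Z peaks for their H3K4ox peaks were spread over several chromosomes. The highest was chromosome 6 from 65 to 70 Mb, with 193 H2A.Z peaks and a mean of 181.5 H3K4ox peaks, followed by chromosome 4 from 30 to 35 Mb (163 and 154), chromosome 4 from 60 to 65 Mb (221 and 216) and chromosome 13 from 85 to 90 Mb (119 and 122.5). There were 64 windows with an H2A.Z excess above 1 log2 unit. They made up 13 of 35 windows on chromosome 6, 11 of 39 on chromosome 4 and 6 of 19 on chromosome 13. On chromosome 1 they were 9 of 47, on chromosome 3 they were 8 of 40, and any other chromosome held at most 3. A deficit of more than 1 log2 unit was found in 71 windows. They made up 13 of 17 windows on chromosome 15, 7 of 16 on chromosome 16 and 3 of 8 on chromosome 22. On chromosome 9 they were 5 of 26, on chromosome 2 only 6 of 49, and any other chromosome held at most 4. The H3K4ox replicates differed in these windows by an SD of 0.08 log2 units over 593 windows.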
